A study of Drosophila melanogaster with 6 samples.

How the data were processed

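Kc cells labelled wild type (3 libraries) and ko (3 libraries) were compared. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was isolated with a magnetic bead kit and libraries followed standard Illumina preparation. The submitters' processing notes name CASAVA 1.7, cutadapt, STAR 2.7.0f and RSEM 1.3.0 with the dm6 genome build. The annotation release, the options of these tools and whether counting used strand are not given in the sources used here. Each deposited file holds RSEM gene-level estimates: an expected count per gene, which need not be whole because reads that fit several genes are shared out, a TPM value, and a transcript length and effective length weighted by isoform abundance, per the file headers. The deposited TPM values are relative to the sum over all genes of a library. The FPKM column was not used here.

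The files list the same 17714 genes, of which 17587 gene identifiers were found in the Ensembl annotation of the same coordinates and 127 were not. Symbols are those of the files, and 1014 of them have since changed. Coordinates, intron numbers and overlaps come from that annotation, with the transcript of most exons giving a gene's intron number. Of 135 called genes that fall under the rule for named genes, 56 share bases with another annotated gene, and their reads could be told apart only in part, since strand use is not stated.

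Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group with a minimum count of 10, quasi-likelihood F-test, Benjamini-Hochberg adjustment). Normalised values are CPM with TMM-scaled totals, and the scaling factors lay between 0.979 and 1.02. The standard error of a log2 fold change is its size divided by the square root of F. Lists fixed before the data were examined (33 lists of pathways, cell type markers and quality signs) and groups by intron number, arm and 1 Mb segment with at least 20 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts adjusted over the list alone use the p-values of a list's own members. Transcript length was tested on the log2 scale with limma for genes with at least 2 transcripts and a mean TPM of at least 5.

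Genes named in the text follow a rule set beforehand. It takes CG14906, the 12 largest fitted rises and 12 largest fitted falls that passed the test with a mean TPM of at least 1 in the higher group and no overlap between the groups, up to 4 called members per list with the lowest adjusted p, and the roX, EcR, Hml and U2 snRNA genes whatever their value. Not every gene that the rule takes is named. Outside the rule, and chosen after their values were seen, are Ldh, RpS19a, RpS5a, Der-1, del, egg and the genes named for length. Where a group had no count, a fold is a bound against 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% binomial interval; both cover counting error only, since reads carried no molecular identifiers.

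Expected counts per library ranged from 9963557 to 18906951. Nuclear rRNA took 3.98%, 0.218% and 0.219% of the counts in WT replicates 1 to 3 and 4.11%, 1.83% and 0.171% in KO replicates 1 to 3. The first principal component of the log2 CPM (79.2% of the variance) parted the groups, and the second (11.8%) parted replicate 1 of each group from the other libraries. WT replicates 2 and 3 agreed far more closely than any other pair: over 5534 genes with whole counts (within 0.005), the chi-square per gene was 1.67 against 3.08 for KO replicates 2 and 3 and 21.0 or more for other pairs. Libraries made from 1 RNA sample could also differ this much, so the data do not show whether these are separate samples. They were kept as 2 samples as the labels list them, with their sum as an alternative.

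Replicate numbers are shared between the groups but no label states a pairing. Deviations from the group means correlated between same-numbered libraries with r of 0.49, 0.13 and 0.34 across genes. Each was over 0.1, the limit used for taking the numbers as pairs. WT replicate 2 correlated about as well with KO replicate 3 (0.32), and WT replicate 3 with KO replicate 2 (0.13). Only the number-1 libraries were thus matched by the data, which do not show a pairing of numbers 2 and 3. The reported test has no block, and a fit with the replicate number as a block was an alternative.

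The procedures were tested on simulated counts drawn from the observed means and trended dispersions with 200 changed genes. For the comparison of KO with WT over 8300 tested genes, 7 of 50 genes changed 1.25-fold, 32 of 50 changed 1.5-fold, 44 of 50 changed 2-fold and 47 of 50 changed 4-fold were recovered, with 5 of 8103 unchanged genes called. A shifted list and a shifted segment were each called, with 0 of the other 32 lists and 0 of the other 117 segments. Far fewer genes were changed than the 4551 called in the data, and no shift of replicate 1 was built in. The recovery and false-call rates for genes therefore need not hold for the data. Genes were drawn independently of each other. The simulation therefore does not show how often lists or segments are called falsely where genes vary together. For length over 4002 genes, 189 of 200 lengthened genes and 11 of 3802 others were called.

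Alternatives set beforehand were RLE, upper quartile and unscaled library totals, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), no count filter and a stricter one (CPM over 5 in at least 3 libraries), an effective-length offset, an adjusted p of 0.01, the block, a mean TPM of at least 20 for length, and leaving out each library. A joint correction for GC content and length was not run, because no genome sequence was used here; length alone was corrected instead. Also added after seeing the data were a mean TPM of at least 5 in each group for length, a fit without replicate 1 of both groups, the sum of WT replicates 2 and 3, and the removal of segment medians.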

Results

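Poly(A) RNA in 6 libraries of Kc cells, an embryonic Drosophila melanogaster line with plasmatocyte-like traits that responds to ecdysone, was sequenced and summarised per gene. There were 3 wild-type (WT) libraries and 3 libraries labelled as knockout (KO) of CG14906, which the reference annotation names Mettl4. The series' title describes CG14906 as acting in m6A methylation of U2 snRNA, an RNA of the spliceosome. Expected counts per library summed to 16678964, 9963557 and 18906951 in WT replicates 1 to 3 and to 14312536, 13012566 and 11301501 in KO replicates 1 to 3. The sample titles of the second group carry the prefix OE, whereas its source and genotype fields say ko, and the group is called KO here after those fields. No label says whether the 3 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

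CG14906 RNA was neither lower nor higher in the libraries labelled KO. It stood at 18.5 ± 1.91 normalised CPM in WT and at 19.7 ± 1.02 CPM in KO (SD, n = 3 in each group). The single libraries held 18.9, 20.1 and 16.4 CPM in WT and 20.3, 18.5 and 20.2 CPM in KO. The fitted log2 fold change was 0.10 (SE 0.10, 95% interval -0.13 to 0.33, adjusted p = 0.435). CG14906 lies on the minus strand of 3R at 16649981 to 16651157 in dm6, has no annotated intron and shares no bases with another annotated gene. With segment medians as an offset its log2 fold change turned to -0.28 (adjusted p = 0.0503), and over the other settings tried it lay between 0.0053 and 0.15 (adjusted p from 0.229 to 0.971). CG14906 was called under none of these settings, so its RNA level shows neither a knockout nor an overexpression. A knockout that leaves the RNA in place would also give no change, so this does not go against the ko label. The 95% interval leaves room for a log2 rise of at most 0.33 in RNA counted to this gene. Every direction given here is that of the libraries labelled KO relative to WT.

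**Figure D1:**
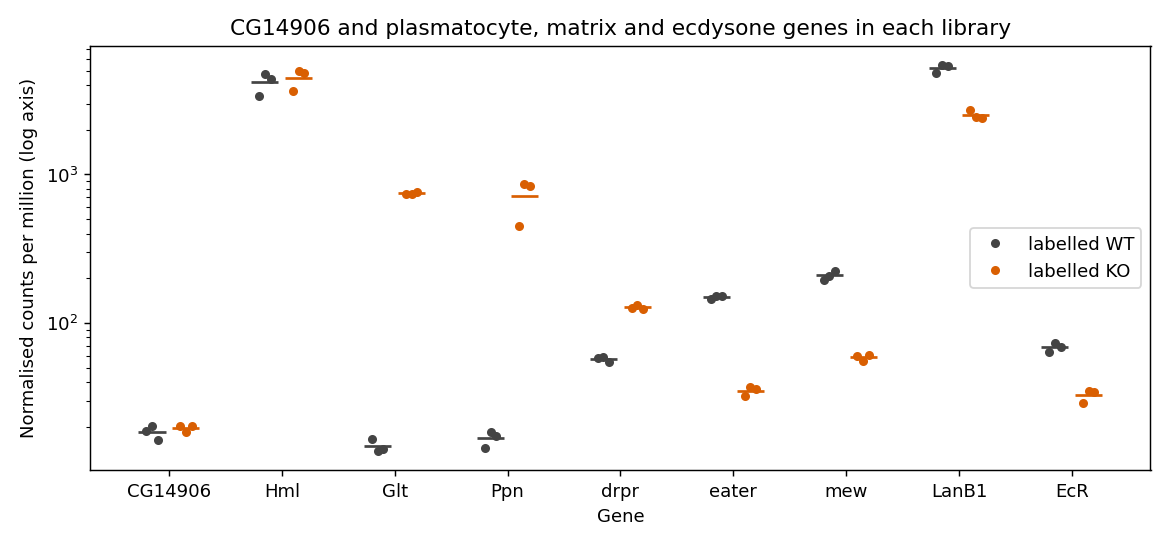
Normalised CPM on a log axis for 9 genes in the 3 WT and 3 KO libraries; each point is a library and each bar a group mean. CG14906 and Hml overlap between the groups, whereas Glt rose from a mean of 14.8 to 748 and eater fell from 150.0 to 35.1.

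The wider comparison asked which genes differed in RNA level between the 2 groups. Of 8405 genes tested, 2324 were higher and 2227 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes numbered 1089, with 771 rises and 318 falls, and 4-fold or larger changes numbered 517, with 386 rises and 131 falls. The groups did not overlap for 63.3% of the genes, where chance gives 10% with 3 libraries against 3. The called genes had a median absolute log2 fold change of 0.52. With WT replicates 2 and 3, which lay closer together than any other pair, summed to 1 sample, 3769 genes were called.

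Several genes went from no reads to steady expression. zpg, a germline innexin of gap junctions, had 0 counts in all WT libraries and 70.8 ± 22.0 CPM in KO, at least 1058-fold higher against a floor of 3 counts over the group. On the same floor CG5048 was at least 129-fold higher, CG13795 at least 98.8-fold, the potassium channel gene Ork1 at least 89.3-fold, the cytochrome P450 gene Cyp9h1 at least 32.0-fold, CG31051 at least 24.5-fold and CG31139 at least 19.8-fold. CG13559 had 1 count in WT and 276 in KO, a ratio of 327 (95% counting interval 58.3 to 12974), and CG34375 had 2 and 283, a ratio of 168 (46.0 to 1392). Cby rose from 0.197 ± 0.014 to 42.3 ± 7.39 CPM, CG5399 from 0.447 ± 0.24 to 65.7 ± 19.97 CPM and fu12 from 0.44 ± 0.15 to 57.1 ± 4.85 CPM. These 12 rises had adjusted p values between 8.72e-07 and 0.00111. zpg, CG13795 and Cby share bases with a gene on the opposite strand, and CG5048 and CG31139 with a gene on their own strand, so some of their reads could not be assigned for certain.

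Falls of the same kind were led by H2.0, a homeobox gene, which went from 11.6 ± 1.87 CPM in WT to 0 counts in KO, at least 147-fold lower. CG18493 was at least 71.1-fold lower and CG7179 at least 48.6-fold lower on the same floor. With 1 count left in KO, the WT to KO ratio was 288 for CG3734 (95% counting interval 51.4 to 11424), 225 for PVRAP (40.1 to 8926), 213 for CG10943 (37.9 to 8460), 187 for CG44435 (33.3 to 7427), 144 for CG44433 (25.5 to 5729) and 85.2 for CR34285 (14.9 to 3397). Osi19 kept 2 counts, a ratio of 101 (27.6 to 837). CG4461 fell from 16.3 ± 0.52 to 0.155 ± 0.070 CPM and the linker histone copy His1:CG33801 from 7.14 ± 2.48 to 0.0992 ± 0.086 CPM. Adjusted p values of these 12 falls lay between 3.35e-06 and 0.000376. PVRAP and CG44435 share bases with another annotated gene, and His1:CG33801 is 1 of many near-identical copies, so its value is uncertain. Histone genes together took at most 0.0052% of the counts of a library (WT replicate 1). Whether poly(A) selection rather than expression set their counts was not tested.

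Plasmatocyte genes, which mark the macrophage-like blood cells that Kc cells resemble, moved in both directions. Of 18 tested, 9 rose and 3 fell, and the counts adjusted over the list alone were likewise 9 and 3. Glt, a glutactin of basement membranes, rose from 14.8 ± 1.56 to 748 ± 8.50 CPM (log2 fold change 5.65, SE 0.09, adjusted p = 2.19e-07), and Ppn, the matrix protein papilin, from 16.7 ± 2.06 to 718 ± 230.5 CPM. The engulfment receptor drpr rose from 57.3 ± 2.37 to 128 ± 3.34 CPM. The phagocytic receptor eater fell from 150.0 ± 3.99 to 35.1 ± 2.42 CPM (log2 fold change -2.10, SE 0.07, adjusted p = 2.27e-06). Hml, a common plasmatocyte marker, stood at 4174 ± 700.4 CPM in WT and 4494 ± 719 in KO (adjusted p = 0.591), with a call only without both number-1 libraries (adjusted p = 0.00812). That fit leaves only WT replicates 2 and 3 in WT, whose spread may be technical. As a set the list did not pass the test against all other genes (camera adjusted p = 0.148; adjusted p = 0.942 with an estimated correlation).

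Of 25 matrix and integrin genes tested, 13 rose and 7 fell, also 13 and 7 adjusted over the list alone. Besides Glt and Ppn, the laminin chain LanB1 fell from 5215 ± 320 to 2515 ± 166 CPM and the integrin alpha chain mew from 209 ± 14.2 to 59.0 ± 2.98 CPM. The set as such was not called (camera adjusted p = 0.476). Other blood cell markers included PPO3, a lamellocyte phenoloxidase, which rose from 0.917 ± 0.023 to 27.5 ± 1.82 CPM, and klu, a crystal cell marker, which rose from 0.665 ± 0.035 to 8.43 ± 0.95 CPM. Among lamellocyte markers 6 of 11 rose and 0 fell (adjusted over the list alone 6 and 0; camera adjusted p = 0.134), and among crystal cell markers 1 of 5 rose and 0 fell (1 and 0; 0.395).

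Germline genes included marked rises. Of 11 germline and ovarian soma markers, 5 rose and 0 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.134). The differentiation factor bam rose from 3.11 ± 0.22 to 52.3 ± 3.14 CPM (log2 fold change 4.06, SE 0.10, adjusted p = 8.72e-07) and its partner bgcn from 33.6 ± 0.058 to 145 ± 12.4 CPM. Small RNA and transposon silencing genes split into 11 rises and 10 falls of 29 (12 and 10 adjusted over the list alone; camera adjusted p = 0.726), with krimp up from 33.5 ± 2.59 to 118 ± 4.68 CPM, zuc from 12.4 ± 0.67 to 28.8 ± 0.52, tej from 2.53 ± 0.47 to 12.8 ± 0.51 and rhi from 1.299 ± 0.20 to 8.35 ± 1.07. Among the falls of that list, chosen after their values were seen, were del (log2 fold change -1.05, adjusted p = 0.00121) and egg (-0.51, adjusted p = 0.000585).

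Ecdysone response genes, the hormone programme Kc cells are known for, gave 6 rises and 5 falls of 22, the same counts over the list alone (camera adjusted p = 0.979). The receptor gene EcR fell from 68.6 ± 4.37 to 32.6 ± 3.29 CPM (log2 fold change -1.07, SE 0.09, adjusted p = 0.000118), while Eip93F rose from 2.45 ± 1.001 to 21.1 ± 6.69 CPM and Eip55E from 671 ± 24.9 to 1700 ± 329 CPM. Among 8 immune genes of the Imd and Toll pathways, 2 rose and 2 fell, also over the list alone (camera adjusted p = 0.758). The Toll effector dl fell from 54.1 ± 1.92 to 19.3 ± 1.31 CPM and the peptidoglycan amidase PGRP-LB rose from 1.60 ± 0.60 to 21.6 ± 5.60 CPM. JAK-STAT and JNK targets gave 4 rises and 2 falls of 12, unchanged over the list alone (camera adjusted p = 0.726), with the TNF ligand egr up from 8.69 ± 1.53 to 80.7 ± 7.02 CPM and the kinase gene hop down from 127 ± 5.73 to 84.5 ± 3.795 CPM.

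Only 2 of the 33 fixed lists passed the set test. Of 30 ribosome biogenesis genes 23 rose and 4 fell (24 and 4 adjusted over the list alone), with Ns1 at 53.1 ± 1.69 CPM in WT and 155 ± 15.7 in KO, Nop56 at 225 ± 5.77 and 417 ± 32.3, and NHP2 at 82.0 ± 6.45 and 165 ± 17.7. Nnp-1 fell from 287 ± 4.45 to 204.6 ± 3.76 CPM, a call that was lost with segment medians as an offset (adjusted p = 0.801). The median log2 fold change of the ribosome biogenesis list was 0.40 (camera adjusted p = 0.00231). Of 73 mitochondrial ribosomal protein genes 37 rose and 4 fell (38 and 4 over the list alone), among them mRpL49 at 27.8 ± 1.31 CPM in WT and 50.5 ± 3.16 in KO, with a list median of 0.22 (camera adjusted p = 0.00564). Both calls were lost with an estimated correlation (adjusted p = 0.942 for each). For mitochondrial ribosomal proteins the estimate was 0.0153, near the preset 0.01, yet the unadjusted camera p rose from 0.000342 to 0.0316. That loss therefore does not show that correlation between these genes made the call. For ribosome biogenesis the estimate was 0.352.

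Of 16 mitochondrial transcripts 11 rose and 0 fell, also over the list alone (camera adjusted p = 0.0527, with the block 0.00583), with mt:ND5 at 355 ± 66.9 CPM in WT and 793 ± 189 in KO. Without WT replicate 1, KO replicate 2 or KO replicate 3 this list was called (0.0484, 0.0463 and 0.00246), as it was under the stricter filter (0.0411), with segment medians subtracted (0.0251) and without both number-1 libraries (0.0348). Of 14 histone genes 0 rose and 2 fell, also over the list alone (0.124, with the block 0.0247, without KO replicate 1 0.00393 and without both number-1 libraries 0.0110). Histone genes took only 0.0017% (KO replicate 3) to 0.0052% (WT replicate 1) of the counts of these poly(A) libraries. Whether poly(A) selection set these values was not tested. Neither list was called with an estimated correlation (adjusted p = 0.942 for each). The fits without WT replicate 1 or both number-1 libraries leave only WT replicates 2 and 3 in WT, whose spread may be technical.

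Splicing factor genes bore most directly on the U2 snRNA that the title names. Of 14 U2 snRNP protein genes 4 rose and 5 fell, also over the list alone (camera adjusted p = 0.944). The U2 auxiliary factor gene U2af50, which the list includes, fell from 179 ± 6.90 to 131 ± 3.88 CPM. The gene snf fell from 107 ± 2.48 to 86.7 ± 2.33 CPM. Sf3b2 rose from 70.3 ± 1.29 to 91.6 ± 2.37 CPM, but stood at a log2 fold change of -0.10 with segment medians as an offset. Of 30 other spliceosome genes 6 rose and 14 fell, also over the list alone (camera adjusted p = 0.319), with LSm7 down from 123 ± 8.10 to 72.4 ± 2.28 CPM and CG3542 up from 52.4 ± 3.66 to 82.5 ± 1.73 CPM, the latter not called with segment medians as an offset (adjusted p = 0.0637). In the m6A list 1 of 12 genes rose and 1 fell, also over the list alone (camera adjusted p = 0.912). These were Ythdf, at 139 ± 5.39 and 161 ± 6.74 CPM (adjusted p = 0.0131), and Mettl14, at 38.5 ± 1.73 and 28.3 ± 1.95 CPM (adjusted p = 0.00263). The call of Ythdf was lost without WT replicate 2 (adjusted p = 0.0621), WT replicate 3 (0.0592) or KO replicate 2 (0.0539), and its log2 fold change of 0.21 turned to -0.03 with segment medians as an offset.

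U2 snRNA itself is not polyadenylated and stood at low levels in these poly(A) libraries. snRNA:U2:34ABb and snRNA:U2:34ABc carried identical values of 4.84 ± 3.64 CPM in WT and 3.74 ± 3.07 CPM in KO, as reads shared between copies would give. snRNA:U2:34ABa stood at 1.86 ± 1.86 and 1.66 ± 1.55 CPM and snRNA:U2:38ABa at 1.44 ± 1.34 and 2.04 ± 1.77 CPM, and none of these 4 copies was called. Their spread came mainly from replicate 1 of each group, with snRNA:U2:34ABb at 9.04 CPM in WT replicate 1 against 2.69 and 2.78 in the others, and at 7.08 CPM in KO replicate 1 against 3.09 and 1.04. Its log2 fold change of -0.37 became 0.45 without WT replicate 1, 0.057 without KO replicate 3 and -1.23 without KO replicate 1. The directions of snRNA:U2:34ABa and snRNA:U2:38ABa also turned when 1 library was left out, as 34ABa went from -0.17 to 1.11 without WT replicate 1, 0.12 without KO replicate 2 and 0.21 without KO replicate 3, and 38ABa from 0.48 to -0.54 without KO replicate 1. snRNA:U2:14B, which the count filter left out, had 4, 5 and 5 counts in WT and 0 in each KO library, at least 3.94-fold lower against 3 counts over the group, and was called in the fit without that filter (adjusted p = 0.0143). Reads of near-identical copies cannot be assigned for certain, so its 14 counts are uncertain. snRNA:U2:38ABb had 0 counts in all libraries. Of 11 tested snRNA genes and 10 tested snoRNA or scaRNA genes, 0 rose and 0 fell, also over each list alone (camera adjusted p = 0.912 and 0.616).

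The remaining lists were not called as sets. Glutathione transferase and oxidative stress genes gave 17 rises and 6 falls of 37 (camera adjusted p = 0.0584), with GstT4 up from 11.7 ± 0.95 to 28.9 ± 2.11 CPM. That list was called without WT replicate 1, KO replicate 2 or KO replicate 3 (adjusted p = 0.0404, 0.0463 and 0.0485) and without both number-1 libraries (0.0348), and not with an estimated correlation (adjusted p = 0.942). Fits without WT replicate 1, here and for the next list, leave only WT replicates 2 and 3 in WT, whose spread may be technical. Lipid synthesis genes gave 11 and 3 of 21 (0.134, without both number-1 libraries 0.0348, with an estimated correlation adjusted p = 0.942), with the lipase gene Lip4 up from 0.0956 ± 0.091 to 12.5 ± 1.79 CPM and SCAP down from 183 ± 1.03 to 141 ± 3.65 CPM. Cell cycle and replication genes gave 11 rises and 22 falls of 52 (0.152; 11 and 23 adjusted over the list alone), with the condensin subunit genes barr and glu down from 167 ± 1.75 to 114 ± 3.54 and from 419 ± 9.07 to 274 ± 10.9 CPM. Unfolded protein response genes gave 7 and 6 of 22 (0.944), ATF4 targets 9 and 4 of 15 (0.306), heat shock proteins 2 and 2 of 19 (0.979), DNA damage genes 5 and 8 of 23 (0.562), oxidative phosphorylation 31 and 7 of 71 (0.174) and glycolysis 3 and 2 of 16 (0.863). Cytosolic ribosomal proteins gave 32 and 13 of 87 (0.562). Apart from cell cycle genes, cytosolic ribosomal proteins (30 and 13) and glycolysis (2 and 2), these counts were the same adjusted over the list alone.

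Markers of other tissues moved in both directions, each with the same counts adjusted over the list alone. Neuron markers gave 4 rises and 2 falls of 7 (camera adjusted p = 0.726), muscle 2 and 0 of 8 (0.562), fat body 3 and 2 of 8 (0.944) and epidermis or imaginal disc 2 and 2 of 7 (0.953). The calcium channel gene cac rose from 12.1 ± 2.15 to 51.0 ± 15.5 CPM, while the sodium channel gene para fell from 13.4 ± 2.805 to 7.21 ± 0.88 CPM (not called on log2(TPM + 1), adjusted p = 0.107) and elav, a neuronal RNA-binding gene, from 45.6 ± 3.89 to 28.1 ± 3.83 CPM (not called with segment medians as an offset, adjusted p = 0.575). Dosage compensation genes gave 1 rise and 5 falls of 11 (0.274), with lncRNA:roX1 at 0.253 ± 0.083 and 1.295 ± 0.36 CPM and msl-1 at 153 ± 7.38 and 108 ± 7.22 CPM. lncRNA:roX2 had between 0 and 3 counts in each library and was not tested. With an estimated correlation the adjusted p of the 33 lists lay between 0.942 and 0.993. Median and mean log2 fold change differed in sign for the immune, unfolded protein response and epidermis lists, and the fat body test pointed up with both below 0. Of the list genes named, Glt, drpr, mew, bam, bgcn, zuc, rhi, EcR, PGRP-LB, egr, Mettl14, Ythdf, Sf3b2, LSm7, CG3542, glu, para, elav, del, egg and lncRNA:roX1 share bases with another annotated gene.

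Genes grouped by intron number, a question raised by the link to splicing, were each tested against all other genes, and no group was called. The median log2 fold change was 0.08 for 867 genes without introns, 0.04 for 2887 with 1 to 2, -0.02 for 3902 with 3 to 9 and -0.05 for 686 with 10 or more. A trend over these groups was not tested. For 715 genes with an intron over 10 kb it was 0.07. In each of the 5 groups the camera adjusted p was 0.582, 0 groups had an unadjusted p under 0.05, and fry called 3.

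Changes followed position along the chromosomes. Genes on 3R were higher in KO, with a median log2 fold change of 0.20 over 2012 genes (camera adjusted p = 1.62e-06), and genes on X and on chromosome 4 were lower, with medians of -0.16 over 1466 genes (0.000192) and -0.37 over 68 genes (2.25e-05). Arm 2R had a median of -0.10 over 1703 genes (0.0293), opposite in sign to its mean of 0.09. The median and mean also differed in sign for 2L and for both groups with 3 or more introns. Medians of 2L and 3L were -0.01 and 0.05 (adjusted p = 0.467 and 0.349). With an estimated correlation 3R kept its call (adjusted p = 0.000469), and 2R, 4 and X lost theirs (0.0652, 0.155 and 0.0652). The estimate for 2R was 0.00495, below the preset 0.01. Its lost call therefore does not come from a higher correlation between its genes.

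Within arms, 62 of 118 segments of 1 Mb were called, 34 up and 28 down, and 9 with an estimated correlation. The first 3 Mb of X held 246 genes with a median log2 fold change of -0.54, 85.0% of them below 0. On 2L the median was 0.42 over 250 genes from 1 to 5 Mb and -0.34 over 383 genes from 15 to 22 Mb. From 10 to 19 Mb of 3R it was 0.35 over 642 genes, 83.2% of them above 0, and this stretch holds CG14906. From 11 to 18 Mb of 3L it was 0.25 over 461 genes, and from 18 to 22 Mb of 2R it was -0.24 over 276 genes. With an estimated correlation all 3 segments of X from 0 to 3 Mb kept their call, as did those starting at 2, 3 and 13 Mb of 2L and at 11, 13 and 15 Mb of 3R (adjusted p = 0.0357 for each). No segment from 15 to 22 Mb of 2L, from 11 to 18 Mb of 3L or from 18 to 22 Mb of 2R kept its call. Some lost it with an estimate below the preset 0.01, as the segment starting at 15 Mb of 2L (-0.0103). Such losses need not reflect correlation between genes. Other groupings of the same libraries, which mix WT and KO, also called many segments, as given in the closing observations.

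**Figure D2:**
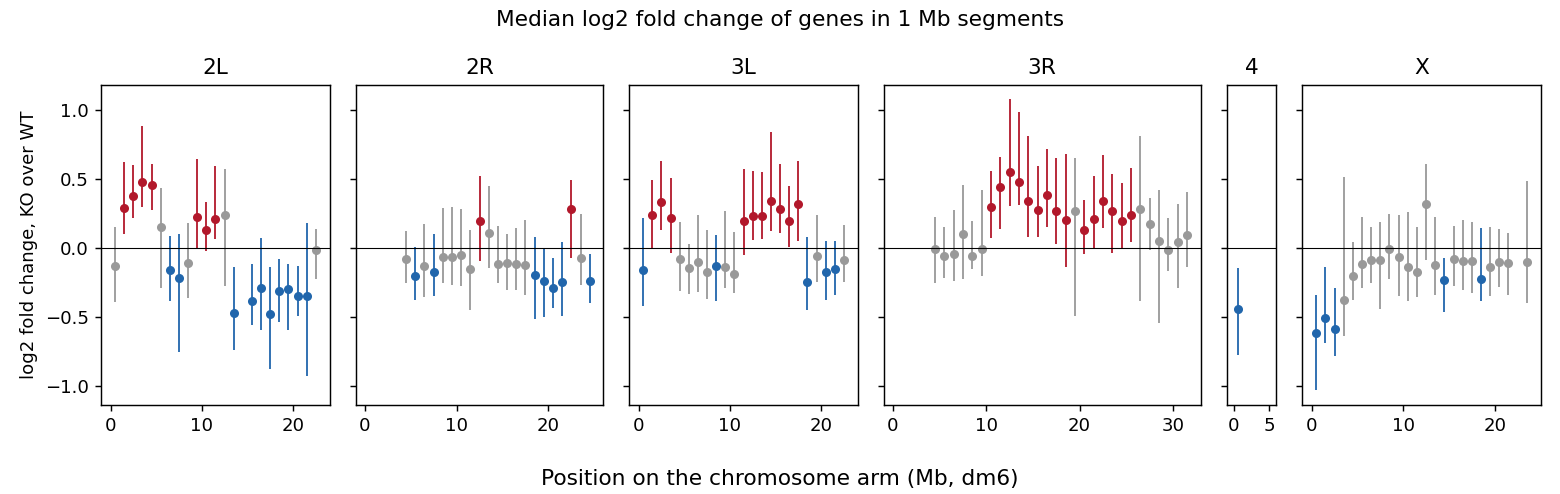
Median log2 fold change of tested genes (points) and their quartiles (lines) in 1 Mb segments along each arm, in dm6 positions; red segments were called higher and blue ones lower in KO, grey ones were not called. Neighbouring segments shift together, as in the first 3 Mb of X (median -0.54) and from 10 to 19 Mb of 3R (0.35).

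Isoform use was read from the abundance-weighted transcript length of each gene. Of 4002 genes with at least 2 transcripts, 65 were longer and 44 shorter in KO (limma adjusted p under 0.05), with a median size of change of 3.57%. With a mean TPM of at least 5 in each group, 99 genes were called. CG7564 shortened from 9082 ± 210.2 to 4522 ± 266 bases and CG5004 from 4185 ± 16.2 to 3716 ± 39.9 bases, while CG42307 lengthened from 1032 ± 13.4 to 1224 ± 11.8 bases (adjusted p = 0.00471 for each). These 3 were chosen after their values were seen, among genes with that level in each group. Changes of at least 10% numbered 17. The count was 9 with the replicate block, 65, 24 and 18 without WT replicate 1, 2 or 3, and 72, 22 and 19 without KO replicate 1, 2 or 3.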

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

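The length test with a mean TPM of at least 5 in each group (99 calls), the fit without replicate 1 of both groups, the sum of WT replicates 2 and 3, the length-only offset and the removal of segment medians were chosen after the data were seen. The count of changed genes (4551) ranged from 3084 at an adjusted p of 0.01 to 5801 without both number-1 libraries, and from 3621 to 4716 when 1 library was left out. Fits without WT replicate 1 or both number-1 libraries rest in WT on replicates 2 and 3. These may come from 1 RNA sample, so calls in those fits may be too many. Changes of at least 2-fold (1089) numbered 609 under the stricter filter, where fewer genes were tested, and 780 to 1336 under all other settings. Called lists (2) numbered 0 with an estimated correlation, 14 with fry, which does not compare a list with other genes, 4 with the replicate block, 7 without both number-1 libraries and 2 to 4 when 1 library was left out. Called intron groups (0) numbered 3 with fry and 0 otherwise. Called segments (62) numbered 9 with an estimated correlation, 100 with fry and 56 to 65 when 1 library was left out. Length calls (109) numbered 17 with a change of at least 10%, 9 with the replicate block, 32 without both number-1 libraries and 18 to 72 when 1 library was left out; the cause was not tested. Beyond length, the mitochondrial transcripts, the histones and Ldh, the replicate block changed no call of a list, an arm, an intron group or a gene named in the results, and gave 5061 changed genes.

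With segment medians as an offset CG14906 turned to -0.28 (adjusted p = 0.0503, not called), Ythdf to -0.028, Sf3b2 to -0.10, PyK to -0.088 and Hml to -0.13. That offset also turned snRNA:U2:34ABa to 0.30 and snRNA:U2:34ABb and snRNA:U2:34ABc to 0.10, and without both number-1 libraries snRNA:U2:34ABa stood at 0.022. Leaving out 1 library gave -0.037 to 0.23 for Hml, -0.54 to 1.54 for snRNA:U2:38ABa, -1.29 to 1.11 for snRNA:U2:34ABa and -1.23 to 0.45 for both snRNA:U2:34ABb and snRNA:U2:34ABc, each lowest without KO replicate 1 and highest without WT replicate 1 except Hml, where these were swapped. The heat shock list, not called in all libraries, was called in the opposite direction without both number-1 libraries (adjusted p = 0.0482). The joint GC and length correction was not run. Depth limits the folds of genes at or under 3 counts in a group to bounds or wide intervals.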

Other observations

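The tests of Ldh against rRNA, of lost genes, of culture history, of replicate 1 over the glycolysis and heat shock lists and of quartiles outside called segments, and the settings without replicate 1 and with segment medians, were chosen only after the results were seen.

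RpS19b rose from 2.34 ± 0.18 to 57.1 ± 20.3 CPM and RpS5b from 1.28 ± 0.29 to 22.8 ± 7.78 CPM. Their paralogs RpS19a and RpS5a, chosen after their values were seen, were not called (log2 fold change 0.039 and 0.07, adjusted p = 0.687 and 0.445). RpL19 fell from 3322 ± 198 to 1488 ± 139 CPM and RpL24 from 2151 ± 149 to 1257 ± 23.4 CPM (SD, n = 3). Within the unfolded protein response list, which was not called as a set, Edem1 fell from 83.3 ± 4.47 to 44.1 ± 0.98 CPM, Edem2 from 163 ± 6.43 to 89.8 ± 4.67 and Herp from 96.1 ± 5.31 to 52.8 ± 4.58, while Pdi rose from 701 ± 61.6 to 1200 ± 51.3. Der-1, chosen after its value was seen, also rose (log2 fold change 0.45, adjusted p = 0.00308). The segmentation and signalling gene ptc rose from 5.61 ± 2.96 to 28.3 ± 4.32 CPM, and pnr, a GATA factor, from 0.355 ± 0.13 to 6.17 ± 2.40 CPM. Of the same epidermis and imaginal disc list, ct fell from 286 ± 17.5 to 174 ± 14.95 CPM and shg from 43.9 ± 4.28 to 35.3 ± 2.78 CPM (adjusted p = 0.0294), the call of shg being lost without WT replicate 2 or 3 (0.0702 and 0.0989) or KO replicate 1, 2 or 3 (0.0606, 0.0505 and 0.0517). With segment medians as an offset shg stood at a log2 fold change of -0.07 (adjusted p = 0.60). Its call was also lost with upper quartile scaling, on log2(TPM + 1), with the length-only offset and with WT replicates 2 and 3 summed. The neighbours CR34285, CG3734 and CG18493, which lie between 19385917 and 19392132 on 3R, were lost together.

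With 3 libraries against 3 there are 10 ways to split the samples, too few for a share under 0.05. The real split gave 4551 changed genes and the highest other split 6, and for changes of at least 2-fold 1089 and 6; 1 of the 10 splits, the real one, gave as many in each case. For length these were 109 and 0, again 1 split. For segments the real split gave 62 and the highest other 49, again 1 split. All 10 splits gave at least the 2 lists called, with 10 the highest, and all 10 at least the 0 intron groups, with 2 the highest. Among the 4 splits that part every same-numbered pair, the other 3 called at most 0 genes, 5 lists and 43 segments. Each other split has both WT and KO libraries on each side. Part of the real difference therefore stays in its contrast, and mixing the groups widens the spread on each side. These splits are thus no null for genes, lists or segments, and cannot decide what chance would give. The other splits called between 2 and 10 lists, so the 2 called lists do not stand out by number.

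Changes shared by neighbouring genes were the first pattern weighed. Medians of adjacent 1 Mb segments correlated with r = 0.72 across 110 neighbouring pairs, where 1000 shuffles of gene positions reached at most 0.30 (permutation p = 0.001, the smallest they can give), which goes against genes placed at random. Removing a trend on length and expression left 59 of the 62 called segments called in the same direction, which goes against such a trend as the whole cause. In called segments the quartile farther from the shift moved 1.705 times as much as the nearer one (median, and 1.12 against genes outside called segments). These segments were called from the same data by a test over all their genes, which favours broad shifts. The ratio therefore does not weigh against a few strongly changed genes per segment. A difference in copy number between the cell populations may be a candidate explanation, since it needs whole segments to move, but these values are not specific to it: DNA was not measured, and regional control of transcription was not tested.

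Replicate 1 stood apart in both groups. Ldh, lactate dehydrogenase, named after its values were seen, was at 367 CPM in WT replicate 1 against 52.3 and 50.5 in the others, and at 124 CPM in KO replicate 1 against 19.1 and 19.4. Ldh was also lower in KO in each same-numbered pair, with a log2 fold change of -1.52 (adjusted p = 0.232) that became -1.48 (adjusted p = 2.84e-05) with the replicate block. The KO library with the second-highest rRNA share had 0.983 times the Ldh of the one with the lowest, although their rRNA shares were 1.83% and 0.171%, but a single library cannot settle whether rRNA carry-over could be the source. Over 10 low-oxygen response genes listed before their values were read, replicate 1 minus the others had a median log2 difference of -0.11 in WT (order-statistic interval -0.41 to 0.36) and 0.22 in KO (-0.32 to 0.54), with members going both ways. Of 16 glycolysis and lactate genes, 14 were higher in WT replicate 1 (median 0.30) and 13 in KO replicate 1 (0.18), and of 19 heat shock genes 12 (0.24) and 16 (1.94). The WT median of the low-oxygen genes met the rule set beforehand for going against a low-oxygen response. That rule did not use the interval, which reached 0.36 in WT, so a low-oxygen response was left undecided.

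Genes gained or lost outright were the last pattern. Taking segment medians as an offset left 3699 genes called, 2976 of them among the 4551 and in the same direction, which goes against regional shifts as the source of most calls. For RNA of another cell population mixed into the KO libraries, 6 genes of at least 5 CPM in WT had 3 counts or fewer over the KO libraries, with lower counting bounds of the WT to KO ratio from 27.6 (Osi19) to 147 (H2.0). Over these 6 genes the counts alone allow a WT-like share of at most 0.680% (H2.0) to 3.62% (Osi19). The genes were picked for their low KO counts, so the size of these bounds followed in part from the choice. That such genes exist did not follow from it, since a WT-like share would leave each at that share of its WT level. For these 6 genes the counts argue against a large WT-like share, if such cells express them as in WT. A smaller share stays possible. A full replacement of the population stays open. No second clone per group was analysed here. Separate culture history or clone of origin therefore cannot be told apart from the genotype that the labels give. Such a history or origin may contribute any part of the 54.1% of tested genes that were called. CG14906 RNA neither bears out the labelled genotype nor goes against it. An effect of that genotype stays among the open explanations, as untested.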
